A study of Mus musculus with 6 samples.

How the data were processed

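Gene counts were analysed for 6 RNA-seq libraries of mouse brain tumours, a model of WNT medulloblastoma, of which the labels name 3 as controls and 3 as carrying a short hairpin RNA against Ift88. Group membership was taken from the sample descriptions. Replicate numbers were given in accession order and pair no samples, so no paired analysis was made.

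Per the labels' protocols, the authors made the libraries from total RNA with a stranded kit (TruSeq Stranded Total RNA). The submitters' processing notes name BWA as a tool and mm9 as the genome build. The counting program, the gene annotation, the strand setting, the BWA version and the handling of reads that match several places are not given in the sources used here. The deposited values are raw counts of reads per gene, as whole numbers with no normalization, in 1 table per library, and no libraries were pooled. Each table held 34591 gene rows and 5 closing tallies, whose names are those that HTSeq-count writes. The tallies were kept out of library sizes and tests. Reads without a feature took 18.8%, 35.0% and 25.6% of all tallied reads in control 1, 2 and 3, and 23.3%, 39.5% and 31.9% in shIft88 1, 2 and 3. Ambiguous reads took 0.943%, 1.60% and 0.876% in the controls and 0.936%, 1.25% and 4.37% in the libraries labelled shIft88. Reads that did not align took 3.44%, 3.48% and 2.93% in the controls and 3.96%, 3.74% and 10.2% in the libraries labelled shIft88.

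Of the gene symbols, 29266 matched a current symbol of the GENCODE annotation at hand, which belongs to a later genome build. That annotation was used for names only, and no coordinates are printed, because an annotation of mm9 was not used here. Because the counting rule is not stated, counts of overlapping genes, antisense partners and near-identical copies (among them the haemoglobin genes, Hspa1a and Hspa1b, and the Xlr3 family) may be split or shared between rows and are uncertain.

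Total gene counts per library ran from 26802618 to 33772559. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept with filterByExpr, which left 16768, libraries were scaled with TMM factors, and the 3 libraries labelled shIft88 were compared with the 3 controls by the two-sided quasi-likelihood test (glmQLFit with robust=TRUE, then glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. No covariate was used, since the labels give none. Levels are counts-per-million values (CPM) computed here from the deposited counts with the TMM-scaled library sizes, as mean ± SD over 3 libraries. Fold changes are log2 of shIft88 over control with their standard errors.

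The 28 gene lists were fixed before the data were examined. The 10 primary lists were the intraflagellar transport complex B, other cilium genes, Hedgehog signalling, WNT signalling, ribosomal proteins, translation factors, ribosome biogenesis, G1/S genes, G2/M genes and regulators of cyclin-dependent kinases. The 17 further tested lists were mature neurons, cerebellar granule and Purkinje cells, neural progenitors, astrocytes, oligodendrocytes, microglia and macrophages, lymphocytes, endothelium, mural cells and fibroblasts, ependyma and choroid plexus, blood, interferon response, hypoxia and glycolysis, ATF4 and unfolded protein response, immediate early and heat shock genes, oxidative phosphorylation, and cholesterol synthesis. A list of sex-linked genes was reported per library and not tested. Lists with at least 3 tested members were tested with camera of limma 3.58.1 (two-sided, inter-gene correlation preset at 0.01) with Benjamini-Hochberg adjustment over 27 lists, and again with an estimated correlation and with fry. The difference given for a list is the median over its members of the log2 fold change minus the median of all tested genes (-0.012).

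The genes named in the text were chosen by a rule fixed before the data were examined: Ift88; up to 12 genes per direction past the threshold with the largest fold change, a mean of at least 1 CPM in the higher group and groups that do not overlap; with fewer than 5 such genes in a direction, the 5 of smallest p with a mean of at least 1 CPM; and from each list up to 4 members past the threshold or, with none, the 2 of smallest p. Gene models without a symbol of their own were counted and not named where a symbol followed in rank. Genes named outside this rule are said to be chosen after their values were seen. Some genes picked by this rule are not reported here.

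The alternatives chosen before the data were examined were DESeq2 size factors in edgeR, library totals alone, DESeq2 1.42.0, limma-voom, robust=FALSE, no filter, a filter of at least 1 CPM in at least 3 libraries, leaving out mitochondrial, haemoglobin, ribosomal RNA and small noncoding RNA genes, leaving out each library in turn, stricter thresholds, the estimated correlation and fry. After the data were seen, 5 more were added: leaving out 15 satellite-annotated gene rows, a term for 3 libraries with more than 100 detected olfactory receptor genes, a term for the mean log2 CPM of the neuron and cerebellar lists, and the 3 libraries with or the 3 without that olfactory receptor signal alone. With 1 library in an arm, that library is assumed to vary like the other group.

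The tests were checked on 5 sets of simulated counts for the 16768 genes of this comparison, with 200 changed genes per set. Each gene had its mean over all libraries and its estimated spread, and library sizes were kept. The test called 0.312% of genes changed 2-fold, 33.0% of those changed 4-fold and 65.4% of those changed 8-fold. These were 1, 113 and 221 genes, and 37 unchanged genes were called over all 5 sets. Genes were drawn independently, without the structure that genes share in the data, so these shares are not detection rates for the data. Camera called 5 of 5 lists that were moved and 0 of 100 that were not, in counts simulated without correlation between genes; in the data the estimated correlation reached 0.814 (G2/M) and 6 to 18 lists passed in each of the other splits of the libraries, so that the simulation does not bound false calls of lists here. Counts per gene were compared between all library pairs, and no pair agreed within sampling noise (smallest chi-square per degree of freedom 107, control 2 against shIft88 2), so no library was taken as a duplicate. After the data were seen, the mean log2 CPM of the hypoxia list per library was also compared between the groups by a linear model, with a 95% interval from the spread between libraries; the part that a term accounts for is its slope times its own difference between the groups. Files holding alignments or reads were not used here.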

Results

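RNA-seq gene counts were collected from brain tumours of a mouse model of WNT medulloblastoma, a tumour of the hindbrain driven by active WNT signalling. The labels name 3 libraries as controls and 3 as sh2-Ift88 (written shIft88 here), for a short hairpin RNA against Ift88, a subunit of the intraflagellar transport complex that builds primary cilia. The series title names primary cilia, translation and the cell cycle, so the comparison asks how these gene groups differ when Ift88 is targeted. Gene counts summed to 30965187, 27876540 and 32709246 in control 1, 2 and 3 and to 33772559, 27267256 and 26802618 in shIft88 1, 2 and 3. The labels do not say that the libraries came from separate animals. The p-values of single genes thus measure the spread between these samples, which may in part be technical. Camera p-values with the correlation preset at 0.01 treat the genes of a list as nearly independent, so they do not measure that spread.

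Ift88 (ENSMUSG00000040040.16) did not differ between the groups by more than the spread between libraries. Its count was 455, 607 and 553 in the controls and 519, 477 and 231 in the libraries labelled shIft88. Scaled for library size this was 15.7 ± 3.47 CPM in controls and 15.05 ± 0.859 CPM in libraries labelled shIft88 (mean ± SD, n = 3 each). The log2 fold change was -0.064 with a standard error of 0.27 (adjusted p = 0.9995, edgeR's quasi-likelihood test), and its 95% confidence interval ran from 61.3% to 149% of the control level. A lower level of the targeted transcript was thus not found in the libraries labelled shIft88, so the labels stand unchecked, and every direction below is that of the libraries labelled shIft88 against the controls. Across the alternatives the log2 fold change of Ift88 ran from -0.39 to 0.13, the latter without control 2. With libraries left out in turn, its lowest value was -0.16. Values of single genes are not relative to the median of all genes, which library totals alone moved to -0.33.

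No single gene passed the threshold between the groups. Of 16768 genes tested with edgeR, 0 were higher and 0 were lower at an adjusted p of 0.05, and the smallest adjusted p was 0.9995. At an unadjusted p of 0.05 there were 541 genes, 330 higher and 211 lower, where 838 would be reached with no effect. The groups did not overlap for 788 genes that were higher and 618 that were lower, together 8.39% of genes, where chance gives 10%. DESeq2 called 45 genes higher and 13 lower, limma-voom called 0, and edgeR without a filter called 5 higher and 1 lower.

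The 5 genes with the smallest p among those higher in libraries labelled shIft88 were Bcas1, Xlr3a, Mov10l1, Fmo2 and Il28ra, and none of them passed the threshold. Bcas1, a gene of the oligodendrocyte lineage, was at 5.66 ± 2.45 CPM in controls and 35.9 ± 8.18 CPM in libraries labelled shIft88, a log2 fold change of 2.67 with a standard error of 0.41. Xlr3a, an X-linked gene with near-identical copies, was at 0.639 ± 0.390 and 13.3 ± 5.37 CPM. Mov10l1, a helicase of the piRNA pathway in germ cells, was at 0.0419 ± 0.0363 and 3.17 ± 1.79 CPM. Fmo2, a flavin-containing monooxygenase, was at 9.18 ± 4.15 and 51.6 ± 18.6 CPM, and Il28ra, the interferon lambda receptor subunit, at 1.58 ± 0.135 and 9.70 ± 3.74 CPM. Among the lower genes, the ephrin receptor Epha7 was at 20.1 ± 8.88 CPM in controls and 1.94 ± 1.24 CPM in libraries labelled shIft88, a log2 fold change of -3.39 with a standard error of 0.58. Emid1 was at 7.14 ± 3.32 and 0.820 ± 0.117 CPM, and Bmp3, a ligand of the BMP family, at 4.24 ± 3.89 and 0.0925 ± 0.0830 CPM. Pfkfb3, which activates glycolysis, was at 43.2 ± 11.3 and 16.1 ± 3.69 CPM, and the oxygen sensor Egln3 at 3.86 ± 2.81 and 0.262 ± 0.164 CPM. All 10 genes kept every library of one group above every library of the other, and their unadjusted p lay between 0.000249 and 0.00204. DESeq2 called each of the 10, and edgeR without a filter called Bcas1, Xlr3a, Mov10l1, Fmo2, Epha7 and the gene model Gm6871. As the 10 were picked by smallest p from the same counts, their separation and these calls add no independent support.

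**Figure D1:**
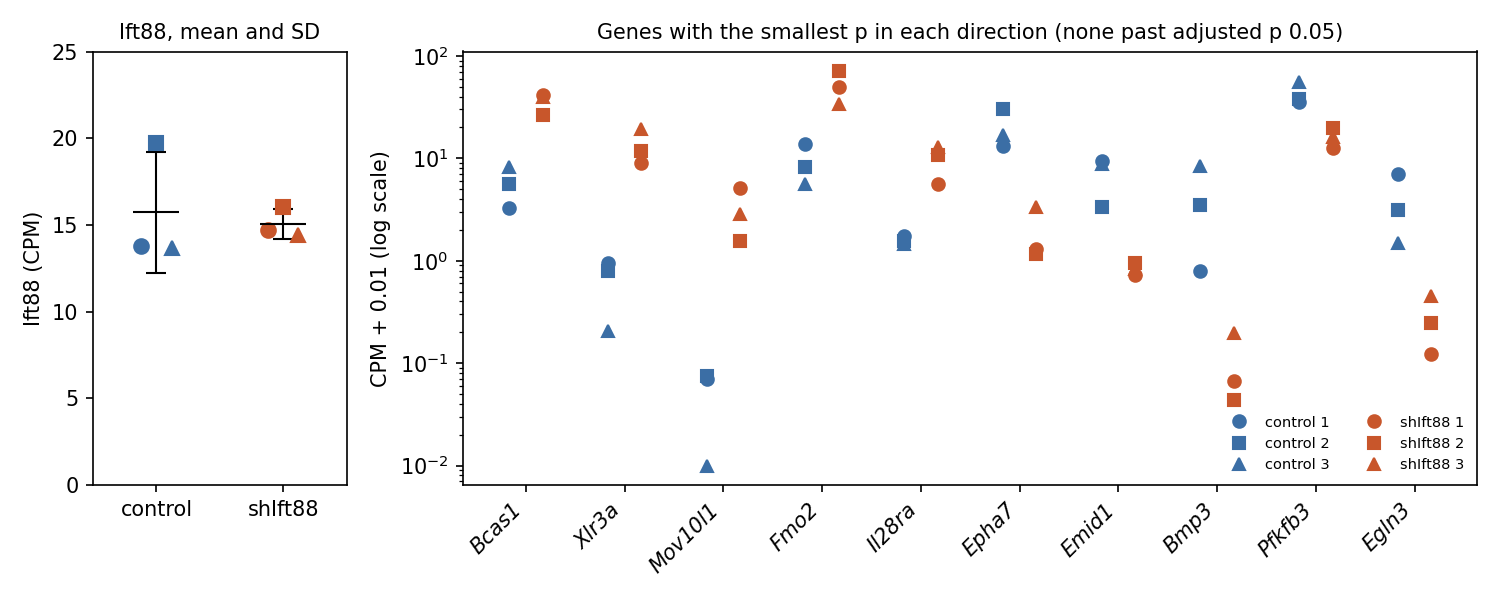
Left, Ift88 in CPM per library with the mean and SD of each group (bars). Right, CPM plus 0.01 on a log axis for the 5 genes of smallest p in each direction, where no control point overlaps the shIft88 points of the same gene, although no gene passed the threshold.

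The lists of cilium genes did not pass between the groups. Of 17 tested genes of the intraflagellar transport complex B, 8 were higher and 9 lower in libraries labelled shIft88, with a median difference of -0.032 and a mean of 0.0024 (log2), and camera, whose direction was upward, gave an adjusted p of 0.817. Ift27 was at 14.3 ± 1.54 CPM in controls and 20.3 ± 1.24 CPM in libraries labelled shIft88, and Traf3ip1 at 18.3 ± 0.245 and 12.9 ± 5.06 CPM, and neither passed. Of 59 other cilium genes, 34 were higher and 25 lower (median 0.053, adjusted p = 0.849). In that list the transition zone gene Rpgrip1l was at 22.2 ± 2.24 and 35.6 ± 6.54 CPM and Ttc21b, of the retrograde transport complex, at 32.2 ± 12.9 and 15.9 ± 5.98 CPM.

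The Hedgehog list, whose signal runs through the cilium, had 13 of 20 tested genes lower in libraries labelled shIft88 and 7 higher, with a median of -0.22, and did not pass (camera adjusted p = 0.0878). Its target gene Gli1 was at 8.11 ± 6.27 CPM in controls and 1.35 ± 0.437 CPM in libraries labelled shIft88, and in control 1 it was at 0.878 CPM, below each library labelled shIft88. Chosen after its values were seen, the target gene Hhip went the other way: it was at 11.9, 0.618 and 0.346 CPM in the controls and at 12.4, 18.2 and 45.04 CPM in the libraries labelled shIft88. For the list, leaving out each library in turn gave adjusted p from 0.0657 to 0.413. The list passed without a filter (median -0.39, adjusted p = 0.0121), where the median of all genes rose from -0.012 to 0.12. It also passed within control 2, shIft88 2 and shIft88 3 (-0.26, 0.0226), where 1 control stands alone.

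The WNT list was lower in libraries labelled shIft88: 21 of 30 tested genes were lower and 9 higher, with a median difference of -0.29 (camera adjusted p = 0.0249; adjusted p = 0.734 with an estimated correlation). No member passed over all genes tested, and 1, Epha7, passed adjusted over the list alone. Kremen1, a receptor of WNT antagonists, was at 161 ± 70.1 CPM in controls and 94.6 ± 14.7 CPM in libraries labelled shIft88. Among list genes chosen after their values were seen, the lowest level in any library was 320 CPM for Axin2, 69.0 CPM for Lef1 and 1346 CPM for Wif1. Chosen likewise, Sp5 was at 2.69 CPM in control 3 and 141.7 CPM in control 1, and Lgr5 at 0.212 CPM in control 1 and 6.35 CPM in control 3. The list median was -0.037 without control 1 (adjusted p = 0.429), -0.19 without shIft88 1 (0.0653), -0.19 without shIft88 2 (0.0297) and -0.49 without control 2 (0.000167). It was -0.15 with a term for the 3 libraries that carry reads of silent genes, described below (adjusted p = 0.158), and turned to 0.13 within those 3, of which 1 is a control (0.560). Nor did the list pass with limma-voom (-0.17, 0.149) or with a filter of 1 CPM (-0.27, 0.0532).

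Among the genes of translation, ribosomal proteins and ribosome biogenesis had slightly lower medians, but their levels overlapped between the groups, and translation factors did not pass. For ribosomal protein the mean level was 8.81, 8.11 and 8.83 log2 CPM in the controls and 8.79, 8.12 and 8.55 in libraries labelled shIft88. For ribosome biogenesis it was 5.80, 5.63 and 6.45 in the controls and 6.07, 5.50 and 5.86 in libraries labelled shIft88. Of 79 ribosomal protein genes, 56 were lower and 23 higher, with a median of -0.11 (camera adjusted p = 0.0497; 0.950 as the adjusted p with an estimated correlation). Rpl36 was at 282 ± 87.6 CPM in controls and 172 ± 34.2 CPM in libraries labelled shIft88, and Rpl35 at 349 ± 86.8 and 235 ± 43.8 CPM. Of 48 genes of ribosome biogenesis, 40 were lower and 8 higher, with a median of -0.20 (adjusted p = 0.0147; 0.950 as the adjusted p with an estimated correlation). Bysl was at 29.8 ± 5.95 and 21.8 ± 2.38 CPM, and Ltv1, of the same list, at 19.5 ± 4.25 and 30.1 ± 10.2 CPM. Of 64 translation factor genes, 36 were lower and 28 higher (median -0.035, adjusted p = 0.488), with Eef2k, the kinase of elongation factor 2, at 28.1 ± 4.04 and 19.1 ± 1.05 CPM and Rps6kb1, the S6 kinase, at 84.7 ± 25.5 and 55.7 ± 14.1 CPM. Without shIft88 2 the ribosomal protein median was 0.085 and that of ribosome biogenesis -0.040, and without control 3 they were -0.0014 and 0.10; none of these 4 passed. The ribosomal protein median was also -0.044 without control 1, where it did not pass, and both lists moved further down without control 2 (-0.33 and -0.38) and without shIft88 1 (-0.25 and -0.35), as ribosome biogenesis did without control 1 (-0.33). Within the 3 libraries that carry reads of silent genes, described below, where control 2 alone stands against shIft88 2 and 3, the ribosomal protein median was 0.20 and camera called it upward (adjusted p = 0.0226). That comparison has no spread among controls. With a term for such reads neither list passed: ribosomal protein turned to 0.12 (adjusted p = 0.202) and ribosome biogenesis was -0.040 (0.884). Nor did the ribosomal protein list pass with limma-voom (-0.12, 0.0501), with a filter of 1 CPM (-0.097, 0.0831) or with haemoglobin and small RNA genes left out (-0.11, 0.0508). Within the 3 libraries without such reads it was 0.056 and ribosome biogenesis -0.048 (0.497 and 0.406). The translation factor list passed without shIft88 1 (-0.15, adjusted p = 0.0171) and without a filter (-0.21, 0.0202). Without a filter the median of all genes, to which lists are compared, was 0.12.

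The G1/S and G2/M lists had lower medians in libraries labelled shIft88, but their levels overlapped between the groups. The mean level of the G1/S list was 5.12, 5.03 and 5.54 log2 CPM in the controls and 5.14, 4.44 and 4.98 in the libraries labelled shIft88. For the G2/M list it was 5.14, 5.56 and 5.89 in the controls and 5.24, 4.16 and 5.74 in the libraries labelled shIft88. Of 54 G1/S genes, 46 were lower and 8 higher, with a median of -0.31 (camera adjusted p = 6.55e-09; 0.782 as the adjusted p with an estimated correlation). The origin licensing factor Cdc6 was at 23.4 ± 10.5 CPM in controls and 10.1 ± 1.35 CPM in libraries labelled shIft88, and Uhrf1, which maintains DNA methylation at replication, at 97.4 ± 26.4 and 49.5 ± 15.4 CPM. Of 55 G2/M genes, 52 were lower and 3 higher, with a median of -0.36 (adjusted p = 5.59e-09; 0.782 as the adjusted p with an estimated correlation). Cdca2 was at 34.1 ± 11.7 and 17.3 ± 5.69 CPM and the mitotic kinesin Cenpe at 73.6 ± 31.2 and 38.1 ± 17.4 CPM. Of 34 regulators of cyclin-dependent kinases, 19 were lower and 15 higher (median -0.051, adjusted p = 0.849), with the inhibitor Cdkn1a at 9.77 ± 3.59 and 4.06 ± 1.90 CPM and Ccng1 at 53.4 ± 20.2 and 91.8 ± 17.0 CPM. The G2/M median rested on shIft88 2: it was -0.046 without that library (adjusted p = 0.637), -0.21 without control 3, -0.55 without control 1 and -0.77 without shIft88 3. The G1/S list passed without each library in turn, with medians from -0.17 without shIft88 2 and -0.21 without control 3 to -0.49 without shIft88 1, but not within the 3 libraries without reads of silent genes, of which 1 is labelled shIft88 (-0.12, adjusted p = 0.0844).

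**Figure D2:**
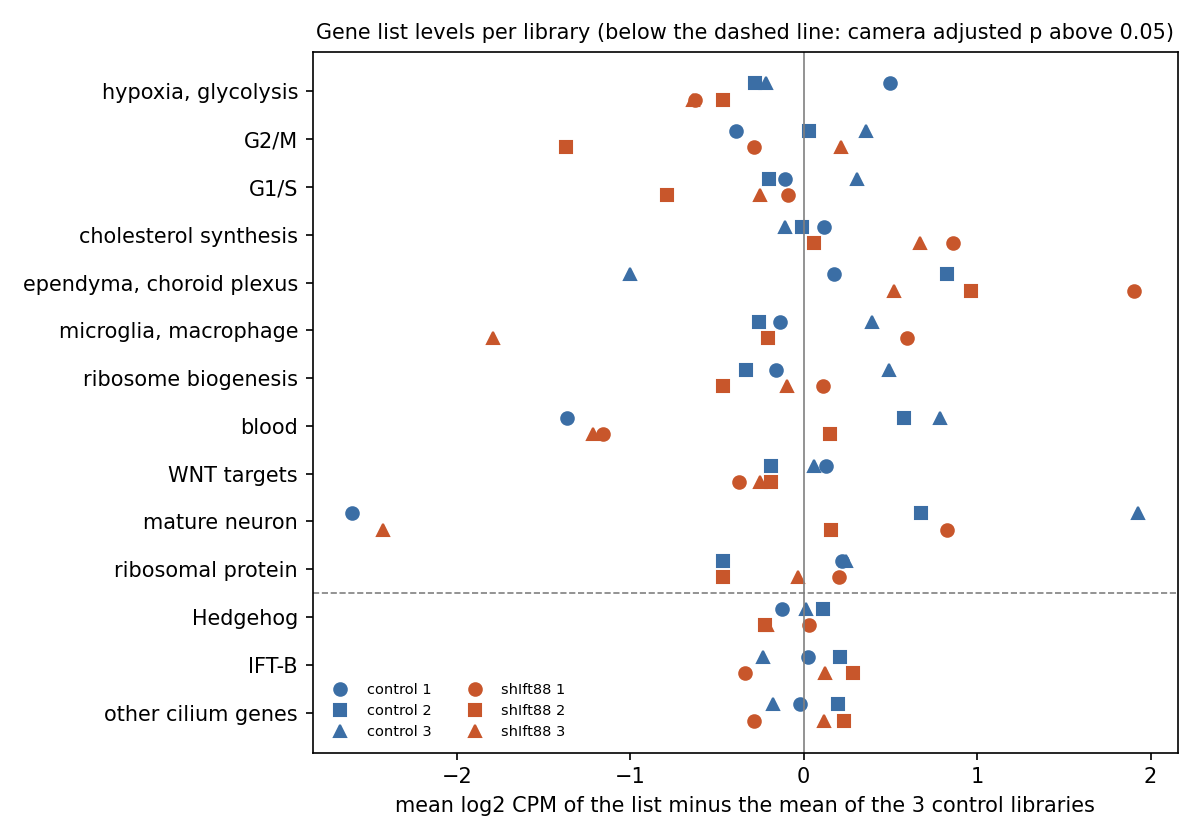
Mean log2 CPM of each gene list per library, minus the mean of the 3 controls, for the 11 lists past the threshold of camera with the preset correlation and, below the dashed line, 3 lists that did not pass. The hypoxia and glycolysis list has all 3 libraries labelled shIft88 below the controls, and the G2/M list has shIft88 2 farthest to the left.

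Genes of hypoxia and glycolysis were lower in libraries labelled shIft88 and genes of cholesterol synthesis were higher. In the hypoxia and glycolysis list 25 of 28 genes were lower and 3 higher, with a median of -0.62, which is 0.650 of the control level (camera adjusted p = 5.59e-09; 0.734 as the adjusted p with an estimated correlation). The mean level of the list was 5.87, 5.09 and 5.15 log2 CPM in the controls and 4.74, 4.90 and 4.73 in the libraries labelled shIft88. Pfkfb3 and Egln3 passed adjusted over the list alone, and 0 members did over all genes tested. Of 25 cholesterol synthesis genes, 21 were higher and 4 lower, with a median of 0.53 (adjusted p = 8.73e-07; 0.734 as the adjusted p with an estimated correlation). Its regulator Srebf2 was at 96.0 ± 14.8 CPM in controls and 193 ± 67.4 CPM in libraries labelled shIft88. The mean level of the cholesterol list was 5.17, 5.05 and 4.95 log2 CPM in the controls and 5.92, 5.12 and 5.73 in the libraries labelled shIft88. In this list shIft88 2 thus lay below control 1. Both lists passed without each library in turn; the hypoxia median was -0.30 without control 1, and that of cholesterol 0.35 without shIft88 1. Within the 3 libraries that carry reads of silent genes, of which 1 is a control, the hypoxia median was -0.15 and did not pass (adjusted p = 0.0714).

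Lists of stress and energy metabolism did not pass with the main settings. The list of ATF4 and the unfolded protein response had 23 of 32 genes higher (median 0.25, camera adjusted p = 0.108), with Nupr1 at 21.1 ± 9.59 CPM in controls and 46.3 ± 22.6 CPM in libraries labelled shIft88 and the cystine transporter Slc7a11 at 47.1 ± 17.7 and 120 ± 99.6 CPM. The interferon list had 20 of 32 genes lower (median -0.23, adjusted p = 0.142), and its 2 genes of smallest p were both higher: Oas1a at 2.78 ± 3.23 and 15.4 ± 14.2 CPM and Usp18 at 4.26 ± 3.06 and 15.1 ± 13.2 CPM. Immediate early and heat shock genes had 14 of 24 lower (median -0.11, adjusted p = 0.0878), with Hspa1b at 12.1 ± 15.4 and 1.99 ± 0.628 CPM and Hspa1a at 2.59 ± 3.03 and 0.462 ± 0.346 CPM. Oxidative phosphorylation had 40 of 60 lower (median -0.063, adjusted p = 0.179), with Ndufa6 at 57.5 ± 15.9 and 91.2 ± 17.0 CPM and Atp5g3 at 198 ± 22.2 and 129 ± 39.9 CPM. With libraries left out in turn, the ATF4 list passed without shIft88 3 (0.34, adjusted p = 0.0151) and the interferon list without control 2 (-0.21, 0.0304). The immediate early list passed without control 3 (-0.36, 0.00568) and without shIft88 1 (-0.60, 0.000681), and oxidative phosphorylation without control 2 (-0.19, 0.00212) and without shIft88 1 (-0.15, 0.00203). With all 6 libraries and no filter, the interferon list (-0.38, 0.0172), the immediate early list (-0.31, 0.00340) and oxidative phosphorylation (-0.24, 0.00274) passed, as the latter did with library totals alone (-0.089, 0.0103). The median of all genes, to which lists are compared, was 0.12 without a filter. The immediate early list also passed within control 2, shIft88 2 and shIft88 3, where 1 control stands alone (-0.65, 5.95e-09).

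Markers of normal cerebellar cells differed more between libraries of one group than between the groups. The mature neuron list had a mean level of -0.55, 2.73 and 3.98 log2 CPM in the controls and 2.88, 2.21 and -0.37 in the libraries labelled shIft88. Between the groups 21 of 24 tested genes were lower, with a median of -0.87 (camera adjusted p = 0.0249; 0.950 as the adjusted p with an estimated correlation), and Stmn2 was at 36.8 ± 26.5 CPM in controls and 4.80 ± 3.36 CPM in libraries labelled shIft88, and Nefm at 3.78 ± 3.78 and 0.928 ± 0.751 CPM. The median of this list was 0.079 without control 3 (adjusted p = 0.411), -0.40 without shIft88 3 (0.644), -1.06 without control 2 (0.111), -1.45 without control 1 and -1.75 without shIft88 1. The neuron list also did not pass with library totals alone (-0.78, 0.567), with a term for the 3 libraries that carry reads of silent genes (-0.77, 0.0959) or within the 3 others (-0.099, 0.221). Its median turned with limma-voom (0.027, 0.455) and with a term for normal tissue built from its own genes (0.028, 0.377). The cerebellar granule and Purkinje cell list had 18 of 22 genes lower (median -0.66, adjusted p = 0.488), with Etv1 at 31.3 ± 4.66 and 20.1 ± 6.35 CPM and Pax6 at 15.2 ± 3.99 and 11.8 ± 2.66 CPM. It was at -0.38, 3.35 and 4.70 log2 CPM in the controls and 3.82, 3.12 and 0.88 in the libraries labelled shIft88. The cerebellar list passed in opposite directions with 1 library left out: its median was -1.26 without control 1 (adjusted p = 2.01e-06) and 0.58 without control 3 (0.00568). Within control 2, shIft88 2 and shIft88 3 it also passed (-0.74, 0.000668).

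Lists of glia and progenitors did not pass with the main settings. Of 16 astrocyte genes 9 were lower and 7 higher, with a median of -0.10 and a mean of -0.20 although camera's direction was upward (adjusted p = 0.669), and Apoe was at 275 ± 56.5 CPM in controls and 516 ± 219 CPM in libraries labelled shIft88 and Gja1 at 206 ± 72.3 and 369 ± 104 CPM. Of 18 oligodendrocyte genes 14 were lower and 4 higher (median -1.02, adjusted p = 0.853). Bcas1 passed adjusted over that list alone and, with Gpr37 at 12.9 ± 5.17 and 47.8 ± 27.5 CPM, was among the 4 higher genes. Of 18 neural progenitor genes 11 were lower (median -0.36, adjusted p = 0.361), with Vim at 668 ± 219 and 450 ± 38.9 CPM and Dlx1 at 9.38 ± 3.84 and 5.14 ± 2.32 CPM. With libraries left out in turn, the astrocyte list passed upward without control 3 (median 0.60, adjusted p = 0.00568) and, although its median was -0.028, without shIft88 3 (0.0187). The oligodendrocyte list passed downward without control 1 (-1.61, 0.00126). The neural progenitor list passed within control 2, shIft88 2 and shIft88 3 (-0.56, 2.34e-05).

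Among other cell types, ependyma and choroid plexus genes had a higher median in libraries labelled shIft88, and microglia and blood genes a lower one. The mean levels of these lists overlapped between the groups. Of 15 ependyma and choroid plexus genes 12 were higher, with a median of 0.72 (camera adjusted p = 0.00546; 0.734 as the adjusted p with an estimated correlation). Kl, made by choroid plexus, was at 0.236 ± 0.213 CPM in controls and 6.50 ± 10.5 CPM in libraries labelled shIft88, where shIft88 1 alone was at 18.7 CPM, and Folr1 was at 0.572 ± 0.475 and 4.72 ± 5.72 CPM. That median was 0.21 without shIft88 1 and 0.40 without control 3, neither of which passed, 1.15 without control 1 and 1.17 without shIft88 3. The ependyma and choroid plexus list did not pass with the filter of 1 CPM (0.39, adjusted p = 0.0959). Its median turned to -0.24 within the 3 libraries that carry reads of silent genes, of which 1 is a control (0.334). Of 26 microglia and macrophage genes 16 were lower, with a median of -0.13 (adjusted p = 0.00819; 0.922 as the adjusted p with an estimated correlation), with Lgals3 at 10.2 ± 7.76 and 2.71 ± 1.08 CPM and Spp1 at 15.3 ± 10.8 and 4.08 ± 2.67 CPM. Its median turned to 0.20 without shIft88 3 and was -0.039 without control 3, neither of which passed, and was -0.048 without shIft88 2, -0.34 without control 1, -0.37 without control 2 and -0.95 without shIft88 1. Nor did it pass with library totals alone (-0.030, adjusted p = 0.168) or with a term for reads of silent genes (-0.033, 0.623). Within the 3 libraries without such reads, of which 1 is labelled shIft88, it turned to 0.59 (0.0508). Of 7 blood genes 6 were lower, with a median of -0.87 (adjusted p = 0.0148; 0.782 as the adjusted p with an estimated correlation), with the transferrin receptor Tfrc at 122 ± 68.3 and 68.6 ± 7.18 CPM and the haemoglobin gene Hbb-b1 at 32.6 ± 23.0 and 14.4 ± 14.2 CPM. With libraries left out in turn, the blood list passed only without control 1 (-1.38) or without shIft88 2 (-1.96), and was -0.60 without control 2, -0.53 without control 3, -0.61 without shIft88 1 and -0.69 without shIft88 3. The blood list also did not pass with library totals alone (-0.86, 0.0877), without a filter (-0.27, 0.0720), within the 3 libraries with reads of silent genes (-0.69, 0.0873) or within the 3 without (-1.82, 0.0748). It did not pass with haemoglobin and small RNA genes left out (-0.61, 0.385). That setting removes members of this list.

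The remaining cell type lists did not pass. Endothelial genes were higher for 11 and lower for 10 of 21 (median 0.041, camera adjusted p = 0.804), with Pecam1 at 14.7 ± 2.22 CPM in controls and 10.96 ± 0.857 CPM in libraries labelled shIft88 and Eng at 6.25 ± 0.719 and 10.5 ± 6.55 CPM. Mural cell and fibroblast genes were higher for 11 and lower for 11 of 22 (median -0.0029, which was 0.048 with library totals alone; mean -0.069, camera's direction upward, adjusted p = 0.817), with Igf2 at 13.7 ± 13.0 and 52.9 ± 46.9 CPM and Slc6a13 at 15.4 ± 11.7 and 52.0 ± 48.2 CPM. Lymphocyte genes were near the detection limit, with 4 higher and 1 lower of 5 tested (median 0.067, mean -0.12, camera's direction downward, adjusted p = 0.599), Il7r at 0.373 ± 0.0346 and 0.182 ± 0.163 CPM and Cd4 at 0.455 ± 0.0597 and 0.517 ± 0.171 CPM.

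Libraries differed in ways that the groups do not follow. Olfactory receptor genes, 1249 in the tables and silent in brain, had a read for 24, 492 and 38 genes in control 1, 2 and 3 and for 31, 564 and 387 genes in shIft88 1, 2 and 3. Satellite-annotated gene rows held 0.0381%, 9.71% and 0.131% of gene counts in the controls and 0.0275%, 6.74% and 44.8% in the libraries labelled shIft88, so that the TMM factor of shIft88 3 was 0.598 and those of the other libraries lay between 1.05 and 1.24. The mean read count per olfactory receptor gene was at most 0.890 in any library. Spearman's rho across genes, which are not independent replicates, was 0.880 to 0.952 between libraries of one group (median 0.932, 6 pairs) and 0.885 to 0.961 between groups (median 0.941, 9 pairs). The first principal component held 47.1% of the variance and ordered the libraries by the mean level of the neuron and cerebellar lists, from control 1 at -0.47 and shIft88 3 at 0.22 to control 3 at 4.33 log2 CPM.

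**Figure D3:**
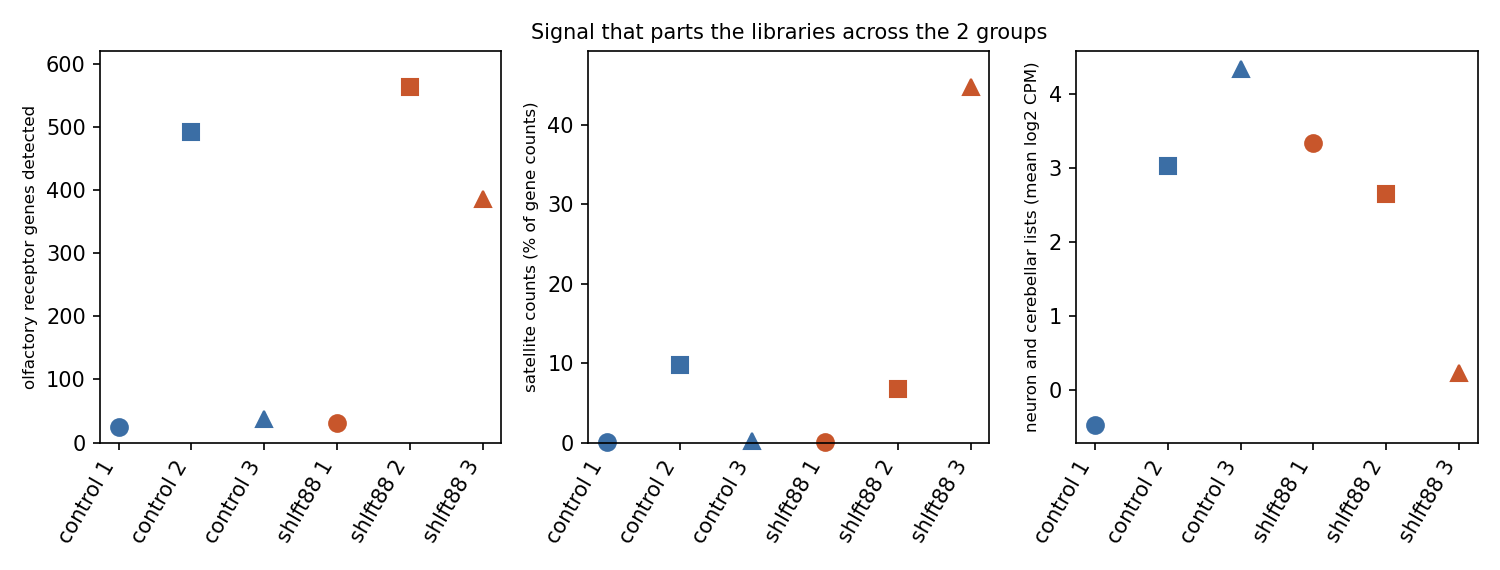
Per library, the number of olfactory receptor genes with a read, the share of gene counts on satellite-annotated rows in percent, and the mean log2 CPM of the neuron and cerebellar lists. Control 2, shIft88 2 and shIft88 3 have 387 to 564 olfactory receptor genes detected, the other 3 have 24 to 38, and the neuron and cerebellar level is lowest in control 1 and shIft88 3.

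The sex-linked list gave mixed signals within libraries. Xist, expressed from the inactive X chromosome of females, was at 10.4, 53.4 and 91.0 CPM in control 1, 2 and 3 and at 54.9, 39.0 and 12.8 CPM in shIft88 1, 2 and 3. The Y-linked gene Ddx3y was at 70.8, 0.0325 and 0 CPM in the controls and at 1.47, 48.9 and 10.7 CPM in the libraries labelled shIft88. Xist and Ddx3y were thus both above 1 CPM in control 1 and in all 3 libraries labelled shIft88. The Y-linked genes Uty, Eif2s3y and Kdm5d likewise had counts in those 4 libraries, from 838 to 1254 in control 1 and from 11 to 21 in shIft88 1.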

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

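Among the tests in this part, the detection of other silent gene families was set before its result was seen, and those of depth, of the satellite counts and of the read shares after; the use of olfactory receptor genes alone as the yardstick was also settled after the values were seen.

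Reads outside the gene counts were more frequent in some libraries labelled shIft88 than in any control. Reads without a feature took 39.5% of all reads in shIft88 2, against 35.0% in the highest control. Ambiguous reads took 4.37% in shIft88 3, against 1.60% in the highest control. Reads that did not align took 3.96% in shIft88 1, 3.74% in shIft88 2 and 10.2% in shIft88 3, against 3.48% in the highest control. Between the groups, the mean share of reads that did not align was 3.28% in controls and 5.95% in libraries labelled shIft88 (exact permutation p = 0.1, the smallest that 3 against 3 can give), with p = 0.5 for reads without a feature and 0.6 for ambiguous reads.

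In control 2, shIft88 2 and shIft88 3, olfactory receptor genes, silent in brain, had reads-per-million rates of 16.9, 22.6 and 16.9 over all tallied reads, against at most 3.52 in the other 3 libraries. Residual genomic DNA is a candidate explanation, since other families silent in brain (207 genes) were detected at least 2.36 times as often in each of these 3 libraries as in any other, while depth is argued against by receptor rates at least 4.79 times as high. Whether such DNA alone accounts for the satellite counts of shIft88 3 stays open: satellite counts per olfactory receptor read were 4.14 times those of the next library, but the other 2 libraries with such reads differed 2.08-fold between themselves, too few to bound the ratio. Transcription of satellite repeats in that library stays open too, as no strand-resolved value decides whether RNA or DNA was read. No biological explanation by group was tested for this pattern, as it holds for 1 control and 2 libraries labelled shIft88.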

How the results depend on the processing

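The settings that leave out satellite rows, add a term for the 3 libraries with reads of silent genes or for normal tissue, or use 3 libraries alone were chosen after seeing the data. Every value below for a list is its median log2 difference relative to all genes, and the cause of a change was not tested unless stated. Of 539 list values under an alternative, 394 kept direction and side of the threshold, 58 kept direction and no longer passed, 20 kept direction and newly passed, and 67 turned direction, of which 3 passed in the new direction: astrocyte (0.60) and cerebellar cells (0.58) without control 3, and ribosomal protein (0.20) within the 3 libraries with reads of silent genes. Of 1132 values of 60 named genes besides Ift88, 1108 kept direction and side, 16 newly passed and 8 turned. Cholesterol synthesis kept its direction in 20 of 20 alternatives and passed in 18, hypoxia and G1/S likewise kept direction and passed in 17, and G2/M in 17. These alternatives reuse the same libraries, and the medians are unchanged with robust=FALSE, the estimated correlation and fry, so their directions could not turn there. Every pass used camera with the preset correlation, so these counts do not measure replication. In simulated counts of this size, 1 of 320 genes changed 2-fold was called, 33.0% of those changed 4-fold and 65.4% of those changed 8-fold. Those counts were drawn without correlation between genes, so the shares are not detection rates for the data. Library totals alone moved the median of all genes to -0.33, and leaving out the filter, with 31004 genes tested, moved it to 0.12. List values are relative to these medians. Without a filter, lists that did not pass thus moved down too: complex B from -0.032 to -0.21 and kinase regulators from -0.051 to -0.23. Blood (-0.87 to -0.27) and neural progenitor (-0.36 to -0.13) moved up. Passes without a filter are therefore not specific to a list. The lymphocyte list had too few tested genes for a value with the filter of 1 CPM.

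The count of genes past the threshold was 45 higher and 13 lower with DESeq2 (1037 adjusted p were not given), 5 higher and 1 lower without a filter, and 0 in both directions with the other settings. With an estimated correlation and with fry, where the median is as given in the report and the test alone differs, none of the 11 lists passed: WNT (-0.29), ribosomal protein (-0.11), ribosome biogenesis (-0.20), G1/S (-0.31), G2/M (-0.36), mature neuron (-0.87), microglia (-0.13), ependyma and choroid plexus (0.72), blood (-0.87), hypoxia (-0.62) and cholesterol (0.53). With library totals alone, mature neuron (-0.78), microglia (-0.030) and blood (-0.86) no longer passed, oxidative phosphorylation passed (-0.089), and mural cells (0.048) and Cd4 (-0.052) turned. With limma-voom, WNT (-0.17) and ribosomal protein (-0.12) no longer passed, and mature neuron (0.027), cerebellar cells (0.26), neural progenitor (0.026), astrocyte (0.16), lymphocyte (-0.060) and mural cells (0.100) turned. Without a filter the median of all genes was 0.12. Hedgehog (-0.39), translation factor (-0.21), interferon (-0.38), immediate early (-0.31) and oxidative phosphorylation (-0.24) passed there. Blood (-0.27) no longer did, and other cilium (-0.12), lymphocyte (-0.11) and endothelial (-0.12) turned. With the filter of 1 CPM, WNT (-0.27), ribosomal protein (-0.10) and ependyma and choroid plexus (0.39) no longer passed and mural cells turned (0.0090). With mitochondrial, haemoglobin and small RNA genes left out, ribosomal protein (-0.11) and blood (-0.61) no longer passed; for blood this setting removes members of the list.

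With the term for reads of silent genes, WNT (-0.15), ribosome biogenesis (-0.040), mature neuron (-0.77) and microglia (-0.033) no longer passed, and ribosomal protein (0.12), translation factor (0.075), other cilium (-0.056), kinase regulators (0.046) and oxidative phosphorylation (0.054) turned. With the term for normal tissue, which is built from their own genes, mature neuron (0.028) and cerebellar cells (0.35) turned, as did astrocyte (0.34) and lymphocyte (-0.0022). Within the 3 libraries without such reads (2 controls), ribosome biogenesis (-0.048), G1/S (-0.12), mature neuron (-0.099) and blood (-1.82) no longer passed, and the following turned: Ift88 (0.061), Dlx1 (0.020), Usp18 (-0.48), other cilium (-0.068), ribosomal protein (0.056), translation factor (0.13), kinase regulators (0.044), neural progenitor (0.20), microglia (0.59), mural cells (0.35), ATF4 (-0.019), immediate early (0.35) and oxidative phosphorylation (0.057). Within the 3 libraries with such reads (1 control), Hedgehog (-0.26), cerebellar cells (-0.74), neural progenitor (-0.56) and immediate early (-0.65) passed, blood (-0.69) and hypoxia (-0.15) no longer did, and the following turned: Kremen1 (0.33), Pax6 (0.026), Cd4 (-0.11), Kl (-0.21), complex B (0.061), other cilium (-0.022), WNT (0.13), ribosomal protein (0.20, which passed as higher), ribosome biogenesis (0.013), lymphocyte (-0.24), endothelial (-0.33), ependyma and choroid plexus (-0.24) and oxidative phosphorylation (0.0048).

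Leaving out each library in turn, the lists and genes with a changed call or direction ranged as follows: Ift88 from -0.16 to 0.13, Cd4 from -0.12 to 0.34, complex B from -0.084 to 0.21, other cilium from -0.083 to 0.17, WNT from -0.49 to -0.037, ribosomal protein from -0.33 to 0.085, translation factor from -0.15 to 0.096, ribosome biogenesis from -0.38 to 0.10, G2/M from -0.77 to -0.046, kinase regulators from -0.085 to 0.067, mature neuron from -1.75 to 0.079, cerebellar cells from -1.32 to 0.58, astrocyte from -0.56 to 0.60, oligodendrocyte from -1.61 to -0.11, microglia from -0.95 to 0.20, lymphocyte from -0.14 to 0.34, endothelial from -0.22 to 0.31, mural cells from -0.35 to 0.15, ependyma and choroid plexus from 0.21 to 1.17, blood from -1.96 to -0.53, interferon from -0.52 to -0.10, ATF4 from 0.023 to 0.35, immediate early from -0.60 to -0.067, and oxidative phosphorylation from -0.19 to 0.065. Calls were gained by cerebellar cells without control 1 (-1.26) and without control 3 (0.58), astrocyte without control 3 (0.60) and without shIft88 3 (-0.028, where the test pointed upward), oligodendrocyte without control 1 (-1.61), ATF4 without shIft88 3 (0.34), interferon without control 2 (-0.21), immediate early without control 3 (-0.36) and without shIft88 1 (-0.60), oxidative phosphorylation without control 2 (-0.19) and without shIft88 1 (-0.15), and translation factor without shIft88 1 (-0.15). No paired analysis was possible because the replicate numbers were given in accession order.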

Other observations

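The tests of the neuronal and hypoxia patterns and the counts of splits for single genes were chosen after the results were seen; the counts of splits for gene lists were set before.

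Several genes differed by large factors between libraries of one group, and are given as values chosen after they were seen. Dct, a melanin synthesis gene, was at 33.3, 372 and 0.198 CPM in control 1, 2 and 3 and at 229, 189 and 318 CPM in shIft88 1, 2 and 3. Cbln1, made by cerebellar granule cells, was at 0.212, 14.0 and 41.1 CPM in the controls and at 198, 19.6 and 0.187 CPM in the libraries labelled shIft88. The pancreatic lipase relative Pnliprp1 was at 6.90, 8.45 and 0.0989 CPM in the controls and at 36.1, 43.5 and 191 CPM in the libraries labelled shIft88. Its levels thus did not overlap between the groups, although no gene passed with the main settings. Wif1, a secreted WNT inhibitor, stayed between 1346 and 3054 CPM in all 6 libraries.

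Most abundant neuronal and cerebellar markers were lower in control 1 and shIft88 3 than in each of the other 4 libraries. With a mean of at least 5 CPM in those 4, 15 of 17 mature neuron genes and 12 of 17 cerebellar genes did so. Snap25 was at 0.545 and 1.06 CPM in control 1 and shIft88 3 and at 44.3 CPM or more in the other 4 libraries. Not all markers followed: in control 1 Stmn2 was at 40.2 CPM, above the 8.78 CPM of control 2, and Etv1 was at 26.5 CPM. Neuronal differentiation of tumour cells alone is argued against, because the mean level of 24 oligodendrocyte and astrocyte genes with a mean of at least 5 CPM was also higher in the other 4 libraries, by 1.99 log2 CPM (95% interval from 1.34 to 2.64 by the spread between libraries). Genomic background is argued against as well, since just 1 of the 2 libraries carries reads of silent genes. Normal cerebellum in the other 4 samples is a candidate explanation that stays open. Chosen after their values were seen, Gabra6, Aqp4, Gfap and Mbp were each at most 1.75 CPM in control 1 and shIft88 3. In each of the other 4 libraries these genes were at 14.5 CPM or more. The astrocyte gene Gja1 went the other way, at 259 CPM in control 1 and 124 CPM in control 3. Oligodendrocyte and astrocyte genes with a mean of at least 5 CPM in those 4 were 24 in number. Of these, 13 (a share of 0.542) were lower in both libraries than in each of those 4. The same held for 9 of 19 microglia and macrophage genes, 6 of 17 endothelial genes and 2 of 19 mural cell and fibroblast genes. A pair set beforehand gives 6.67% by chance, but this pair was picked for its low neuronal markers. The genes were chosen by their level in the other 4 and are not independent, so that share is no yardstick. No biological explanation by group was tested, as the 2 libraries come from different groups.

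The hypoxia and glycolysis list was lower in libraries labelled shIft88 by a median of -0.62 and passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.734) or with fry (0.943), and by the spread between libraries its mean level differed by -0.58 log2 CPM (95% interval from -1.29 to 0.14). Control 1 as the sole cause is argued against, since without it the level still differed by -0.327 (interval from -0.57 to -0.089). Of the -0.58, a term for normal tissue accounted for 0.025 (interval from -0.018 to 0.068). The level of normal tissue was 2.29 log2 CPM in controls and 2.07 in libraries labelled shIft88. As these are close, the term could account for little. The difference left with it was -0.60 (interval from -1.25 to 0.049), which includes no difference. Normal tissue is thus argued against as the whole cause only as far as this level measures it. Reads of silent genes stay open as a cause of part or all of the difference. A term for them accounted for -0.058 (interval from -0.37 to 0.26), but the difference left with that term was -0.52 (interval from -1.47 to 0.43), too wide to decide. Within the 3 libraries with such reads (1 control) the median was -0.15. The hypoxia list was examined because its camera p was the smallest, and these intervals do not allow for that choice. The hairpin, the oxygen supply of the sampled tumour and the handling of tissue also stay open, since Ift88 itself was not measurably lower and no label records the others. With 10 splits of the 6 libraries, too few for a share under 0.05, 1 gave a camera p as small, the real one (3.44e-10; smallest other 1.07e-06).

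With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At the adjusted threshold 10 of the 10 splits gave as many genes (real 0, highest other 0). With a real count of 0 this outcome was fixed in advance and tells nothing about the groups. At an unadjusted p of 0.05, 8 gave as many genes as the real split (541). The highest other was 1739, for control 1, shIft88 2 and shIft88 3 against the rest, which points to a structure of the samples other than the groups. The Y-linked gene Uty was at 38.0, 32.8 and 8.18 CPM in these 3 libraries, against at most 0.424 CPM in the rest. The mean level of the neuron and cerebellar lists was also lowest in them, at -0.47, 2.65 and 0.22 log2 CPM. These traits go together here and cannot be told apart. The split is uneven across the groups, with control 1 on the side of shIft88 2 and shIft88 3. The traits therefore overlap in part with the groups, and no alternative adjusted for this split or for Y-linked genes. As many lists past the threshold came from 5 of the 10 splits (real 11, highest other 18). A camera p as small was given by 3 splits for WNT (real 0.00846, smallest other 0.000166), 5 for ribosomal protein (0.0202, 2.05e-32), 7 for ribosome biogenesis (0.00381, 3.23e-17), 2 for G1/S (7.28e-10, 3.75e-13), 4 for G2/M (4.14e-10, 4.61e-43) and 3 for cholesterol synthesis (1.29e-07, 4.18e-09).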
